A study of Mus musculus with 40 samples.

How the data were processed

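Poly(A) RNA of mouse embryonic stem cell aggregates was sequenced in 40 libraries, 4 for each of 10 groups (untreated and XAV939 aggregates at days 3, 4, 5, 6 and 7). Per the labels' protocols, RNA was extracted with Trizol, stranded TruSeq libraries were made from 300 ng of RNA, and each was read as 81 bp pairs on a HiSeq 4000, with 36 M reads as the target. Per the submitters' processing notes, bcl2fastq 2.20.0 was run and the genome build was mm10. The aligner, the counting program, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table holds raw counts per gene, as whole numbers that sum to between 30197759 and 44086019 per library, and the deposited values carry no normalisation. Whether reads or read pairs were counted is not stated. Its columns were matched to the samples by day, arm and replicate number in the titles, and all 40 were used.

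The table has 26906 genes, of which 508 (1.89%) had 0 counts in every library. For coordinates and transcript lengths 26857 gene identifiers were matched to GENCODE release M21 and 49 were not. The table was checked for libraries counted more than once: over the 60 pairs of libraries of 1 group the smallest chi-square per gene was 10.9, so no pair was a copy or a split of 1 library.

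Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. filterByExpr on the 10 groups (minimum count 10, minimum total count 15) left 16878 genes. Counts were scaled with trimmed means of M values (TMM), and 1 quasi-likelihood model with a mean for each group and robust dispersion was fitted to all 40 libraries, so that all groups shared 1 estimate of the spread (30 degrees of freedom, with a prior of 5.19). The contrasts were XAV939 against untreated at each of the 5 days, day 7 against day 3 in each arm, the change of the XAV939 effect from day 3 to day 7, and an F test of the 5 effects together. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are CPM with TMM-scaled totals, and fold changes against a group with 0 counts in every library are given as lower bounds from 3 counts over the group. Such floors cover counting error only.

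Gene lists for lineages, signalling pathways, epithelium, stress and mitochondria were written before the data were examined, and 41 lists with at least 4 tested members were tested with camera at a preset correlation of 0.01 on log2 CPM (prior count 2), with camera at an estimated correlation and with fry, adjusted over the lists of 1 contrast. camera compares the members with the other genes, whereas fry asks whether the members move on balance one way. Counts of members are also given adjusted over the list alone.

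Named genes were chosen by a rule written before the data were examined. It takes, for each contrast, the 6 largest rises and falls among called genes with a mean of at least 5 CPM in the higher group and groups that do not overlap, 2 to 4 members of each list described (those with the smallest adjusted p, or the highest mean where fewer than 2 passed), and a fixed panel of marker genes at every day. The text names these from the top. Ido2 and Unc45b fall outside the rule and were named after their values were seen.

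Alternatives written before the data were examined were size factors by relative log expression, DESeq2 1.42.0, no filter on low counts, a filter of 5 CPM in 4 libraries, an absolute log2 fold change of at least 1, fits of only the libraries compared, the replicate number as a block, and each library left out in turn. Replicate numbers pair the arms: within a day the deviations of libraries with the same number correlated across genes at 0.214 to 0.77 in all 20 pairs, and each of the 20 libraries correlated best with the library of its own number. Between day 3 and day 7 the 8 such correlations ran from -0.136 to 0.374 and 2 were highest for the own number, so libraries were taken as paired within a day only. Nearer days were not compared in this way, so a pairing between them is not excluded. Length and GC offsets (smooth trends of each library on transcript length and GC content), a block within each day, both together, a block in the fits of 1 day, the data without day 4 untreated library 1 and day 6 untreated library 3, and tests of the effect between days were added after the data were seen.

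The edgeR steps were tested on simulated counts of 16758 genes drawn from the fitted means and dispersions. Of genes changed 2-fold 53.1% were recovered at day 5 and 63% at day 6, and of genes changed 4-fold 87% and 85.7%. Of the calls 4.14% at day 5 and 3.29% at day 6 were false. At day 7 90% of the 4-fold changes were recovered. The list tests were run on simulated counts of 16764 genes in which all 14 members of 10 lists rose 4-fold at day 5, and camera found all 10 and called 0 of 31 unchanged lists. The simulated genes varied independently and the lists held random genes, so false calls that correlated members cause could not show there. The simulated counts held no pairs of libraries and no library that stood apart, so the recovered shares need not hold for the real libraries. Results of some genes are not reported here. Figures were drawn with matplotlib 3.10.9.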

Results

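RNA was sequenced from mouse embryonic stem cells (line CGR8, strain 129) gathered into epiblast-like aggregates in a serum-free medium. Some aggregates received XAV939, a tankyrase inhibitor that stabilises Axin and so lowers Wnt/β-catenin signalling, from 0 to 72 h, and the others were left untreated. Both arms were sampled at days 3, 4, 5, 6 and 7, with 4 libraries in each of the 10 groups and 40 libraries in all. The deposited total per library ran from 30197759 to 44086019 counts, with a median of 35740000. Levels below are CPM, counts scaled to a common library total, given as the mean ± SD of 4 libraries. Fold changes are XAV939 over untreated on the log2 scale unless another order is named, each with its standard error (SE), and adjusted p-values come from the edgeR quasi-likelihood test over 16878 genes. These p-values measure only the spread between these libraries, since the labels do not say whether replicates were separate cultures. The labels of the untreated libraries say that no matrigel was used and those of the XAV939 libraries do not mention it. A difference in matrigel between the arms, if there was one, is not separated from XAV939 in any comparison below.

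The first comparison asked how the aggregates changed between day 3 and day 7 with and without the inhibitor. Of 17 tested genes of the core and primed epiblast list, 15 fell in each arm, and all 12 tested Hox genes of paralogue groups 1 to 4 rose. These were 2 of the 27 lists that camera called in untreated aggregates, 21 up and 6 down, and of the 22 called in XAV939 aggregates, 17 up and 5 down. None of them kept its call with an estimated correlation, where the epiblast list had adjusted p = 0.0792 and 0.11 and the Hox list adjusted p = 0.0985 and 0.123 in the 2 arms. With fry, which does not compare members with the other genes, all 27 and all 22 were called. Pou5f1 (chromosome 17, 35506018 to 35510772, mm10), the gene of the pluripotency factor Oct4, fell from 788 ± 88.3 to 4.25 ± 4.46 CPM in untreated aggregates and from 803 ± 84.8 to 2.99 ± 1.26 CPM in XAV939 aggregates. Nanog, another pluripotency factor, fell by 7.10 on the log2 scale (SE 0.535, adjusted p 1.49e-13) in untreated aggregates and by a log2 fold change of -6.48 (SE 0.52, adjusted p 5.58e-13) in XAV939 aggregates. The DNA methyltransferase Dnmt3b fell from 1800 ± 222 to 115 ± 26.6 CPM without the inhibitor and from 1840 ± 318 to 83.5 ± 15.7 CPM with it.

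Hoxd3, a Hox gene of the hindbrain and trunk, had 0 counts in all 8 day 3 libraries. At day 7 it reached 59.5 ± 9.2 CPM in untreated and 58.6 ± 26.9 CPM in XAV939 aggregates, at least 2900-fold and 2560-fold higher against a floor of 3 counts over the group. The annotation of Hoxd3 overlaps that of Hoxd4 on the same strand, so the counts of either may hold reads of the other. Cdh2, the N-cadherin gene of the pan-neural progenitor list, rose by 5.56 (SE 0.306, adjusted p 1.82e-16) in untreated aggregates and by 5.58 (SE 0.307, adjusted p 1.3e-16) in XAV939 aggregates. The pan-neural genes Sox1 and Pax6 rose 90.3-fold and 135-fold without the inhibitor and 177-fold and 152-fold with it. In untreated aggregates Hoxb9 of the trunk rose 268-fold, Foxc1 of the paraxial mesoderm 317-fold and Kdr, the receptor that marks endothelial precursors, 450-fold. Otx2, an epiblast and anterior neural factor, fell 4.02-fold in both arms, and Six3, a forebrain factor, reached 1.96 ± 0.609 and 2.21 ± 0.824 CPM at day 7. In total 5855 genes rose and 5495 fell in untreated aggregates, and 6203 rose and 5758 fell in XAV939 aggregates. The groups did not overlap for 65.9% and 64.1% of the genes tested, where chance gives 2.86%. In untreated aggregates the log2 fold change of Pou5f1 was -8.59 instead of -7.53 without day 7 library 2. That of Pax6 was 7.76 instead of 7.08 without day 3 library 3, and that of Foxc1 9.07 instead of 8.31 without day 3 library 2.

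**Figure D1:**
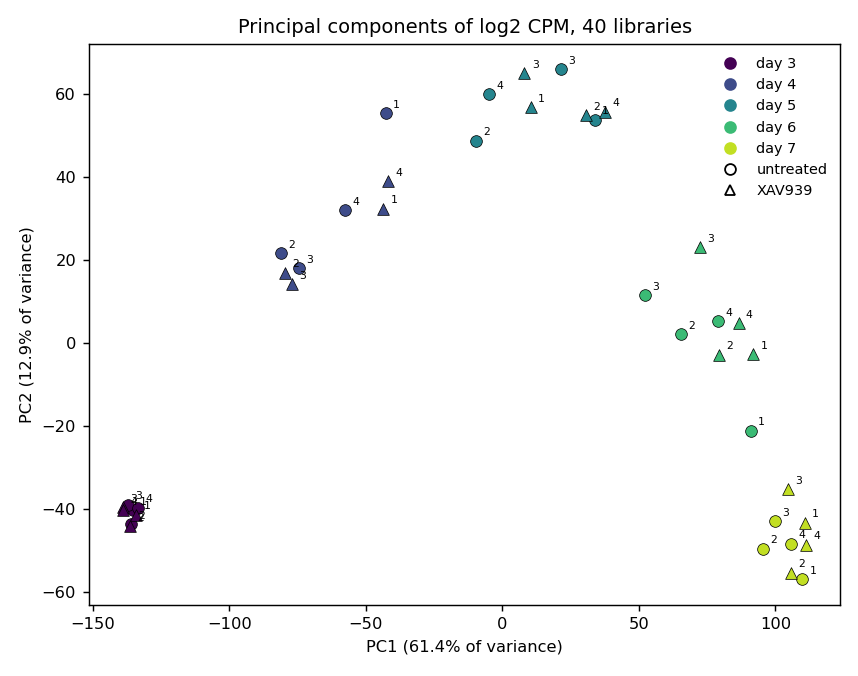
First and second principal components of log2 CPM, with 1 point for each of the 40 libraries, coloured by day, shaped by arm and numbered by replicate. The first axis holds 61.4% and the second 12.9% of the variance, and libraries of day 3 lie at one end of the first axis and those of day 7 at the other.

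At day 3, at the end of the treatment, 1 gene was called between the arms in the fit without pairing. Ido2 (chromosome 8, 24531892 to 24576333), a tryptophan-degrading enzyme named here after its values were seen, fell by 2.06 on the log2 scale (SE 0.363, adjusted p 0.0336), from 0.71 ± 0.104 to 0.167 ± 0.0396 CPM. edgeR called 0 genes higher. Of the 16878 genes tested 309 had an unadjusted p under 0.05, less than the share of 0.05 that no effect would give. This fit leaves out the pairs of libraries within a day, so few calls do not show that the arms were alike. DESeq2 called 0 genes higher and 1 lower. Of 14 tested Wnt/β-catenin target and feedback genes 12 had negative fold changes, with a median of -0.31, and camera did not call the list (adjusted p 0.142). Axin2, a direct target and negative regulator of Wnt signalling, was at 14.9 ± 5.04 CPM with XAV939 and 18.1 ± 2.97 CPM without (adjusted p 1). Tcf7, a transcription factor of the pathway, was at 108 ± 30.6 and 122 ± 32.1 CPM (adjusted p 1). T (brachyury), the primitive streak factor, was at 0.816 ± 0.136 and 1.84 ± 0.325 CPM. With 1 library left out the call of Ido2 held only for untreated library 4. Its adjusted p was 0.193 without untreated library 1, 0.145 without untreated library 2 and 0.108 without untreated library 3. It was 0.107 without XAV939 library 1, 0.33 without XAV939 library 2, 0.466 without XAV939 library 3 and 0.187 without XAV939 library 4. A block of replicate number within each day gave 0.0612, with a log2 fold change of -2.08, and no filter on low counts gave 0.0915. A fit of the 8 day 3 libraries with a block kept the call, with 1 gene higher and 12 lower in all, and length and GC offsets with the block within each day gave 3 and 4.

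At day 4 the primitive streak genes T and Mixl1 fell in XAV939 aggregates, with most of the difference carried by 1 untreated library. T (chromosome 17, 8434423 to 8442496) fell by 4.87 (SE 0.832, adjusted p 0.011), from 151 ± 266 to 5.15 ± 2.65 CPM. Mixl1, a homeobox factor of streak and mesendoderm, fell by 5.82 (SE 0.999, adjusted p 0.011), from 44.1 ± 82.2 to 0.782 ± 0.283 CPM. Mcc, a gene mutated in colorectal cancers, fell by 1.88 (SE 0.34, adjusted p 0.0179). XAV939 libraries held 2.59 to 7.8 CPM of T and 0.511 to 1.1 CPM of Mixl1, below every untreated library. In untreated library 1 T stood at 550 CPM and in the other 3 between 11.8 and 24.6 CPM. Mixl1 stood at 167 CPM there and between 2.06 and 4.17 CPM in the others. All 3 calls ended without this library, where the log2 fold changes of T, Mixl1 and Mcc were -1.80, -1.95 and -1.05 and every adjusted p was 1. They also ended without XAV939 library 1 (adjusted p 0.15 to 0.235), XAV939 library 3 (0.0797) and XAV939 library 4 (0.0695 to 0.0703), and with the replicate number as a block (0.0775 to 0.0956, and 0.24 with the block within each day, where the log2 fold change of T was -2.72). The same held with no filter on low counts (0.0572) and in a fit of the 8 day 4 libraries with a block (0.513 to 0.536).

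edgeR called 0 genes higher and 3 lower at day 4, with 944 genes at an unadjusted p under 0.05, and DESeq2 called 18 higher and 38 lower. Without untreated library 2 edgeR called 0 higher and 7 lower, without untreated library 3 it called 4 and 44, without untreated library 4 it called 23 and 32, and without XAV939 library 2 it called 8 and 5. It called 0 in either direction without untreated library 1 or without XAV939 library 1, 3 or 4. All 14 tested primitive streak and mesendoderm genes had negative fold changes, with a median of -2.57, of which 2 fell over all genes tested and 12 adjusted over the list alone (camera adjusted p 3.18e-12). The Nodal/Activin target list was also called down (adjusted p 2.91e-06, 0 of 10 members over all genes and 5 adjusted over the list alone). Its member Tdgf1, the Nodal co-receptor, was at 45.2 ± 33.7 CPM with XAV939 and 177 ± 168 CPM without (adjusted p 0.32). The log2 fold change of Tdgf1 was -1.97, -1.09 without untreated library 1 and -2.62 without XAV939 library 2. The forebrain and anterior neural list was called up, with 13 of 15 tested members positive and a median of 0.72 (adjusted p 6.54e-05), 0 members over all genes and 2 adjusted over the list alone. Among them Otx2 was at 152 ± 29.8 and 127 ± 37.4 CPM and Hesx1, a homeobox factor of the anterior neural ridge, at 7.19 ± 10.1 and 1.14 ± 1.03 CPM. XAV939 library 1 held 22.3 CPM of Hesx1 against 1.31 to 3.14 CPM in the other 3, and without it the log2 fold change was 0.916 instead of 2.66. With an estimated correlation these 3 lists each had adjusted p = 0.16, and none of the 16 lists called at day 4, 7 up and 9 down, kept its call. Without replicate 1 camera called 8 lists, of which 6 were among the 16. The primitive streak, Nodal/Activin and forebrain lists were among these 6. The Wnt/β-catenin target list, called down with 12 of 14 members negative (adjusted p 0.0439, and adjusted p = 0.517 with an estimated correlation), was not called then (adjusted p 0.793).

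At day 5 camera called 22 lists down in XAV939 aggregates, among them Hox, somitic, endoderm and epithelial lists, and 3 up, among them the pan-neural list. With an estimated correlation 6 of these 25 lists kept their call, all of them down. Hox genes of paralogue groups 5 to 8, which mark the trunk, had the lowest median of the lists called, -3.19, and 10 of 11 tested members fell (camera adjusted p 2.49e-17, 10 adjusted over the list alone). Hoxb8 fell from 10.6 ± 13.8 to 1.39 ± 0.82 CPM, and Hoxa7 and Hoxc6, both under 1 CPM, fell 16.5-fold and 31.3-fold. Of 12 Hox genes of paralogue groups 1 to 4, 6 fell, among them Hoxc4 (log2 -3.55, SE 0.687) and Hoxd4 (log2 -3.16, SE 0.596), with 10 adjusted over the list alone (adjusted p 1.37e-13). Hoxb9 fell from 25 ± 33.4 to 3.78 ± 2.06 CPM, and Hoxaas3, an antisense RNA whose reads may be those of Hoxa3 or Hoxa7 on the other strand, fell by 3.64 (SE 0.755). Presomitic and somitic mesoderm genes fell in 7 of 18 cases (adjusted p 4.94e-08, 10 adjusted over the list alone). They included Aldh1a2 (chromosome 9, 71215789 to 71296243), the enzyme that makes retinoic acid, which fell 33.2-fold (SE 0.715 on the log2 scale, adjusted p 0.000256) from 69 ± 98.5 to 2.07 ± 1.53 CPM. The forkhead gene Foxc2 fell 16.6-fold, the somite homeobox gene Meox1 9.78-fold and Tbx6, a factor of presomitic mesoderm, 7.29-fold. Cyp26a1, the enzyme that degrades retinoic acid, fell from 36.2 ± 15.7 to 8.34 ± 2.86 CPM, and the Wnt ligand gene Wnt2b from 5.13 ± 4.08 to 0.783 ± 0.378 CPM. Arg1, the arginase gene, fell 15.1-fold (adjusted p 0.000256). Untreated library 1 held 75 CPM of Hoxb9 against 7.29 to 10.2 CPM in the other 3 and 216 CPM of Aldh1a2 against 4.82 to 35 CPM. Without untreated library 1 the calls of Hoxb8, Hoxc4, Hoxa7, Hoxc6, Hoxb9, Hoxaas3, Meox1, Tbx6, Cyp26a1 and Wnt2b ended, at adjusted p between 0.052 and 0.235. The log2 fold change was then -1.42 instead of -2.93 for Hoxb8, -1.85 for Hoxc4, -2.44 instead of -4.04 for Hoxa7, -2.78 instead of -4.97 for Hoxc6 and -1.14 instead of -2.72 for Hoxb9. It was -1.65 for Hoxaas3, -1.37 instead of -3.29 for Meox1, -2.17 instead of -2.87 for Tbx6 and -2.03 instead of -2.70 for Wnt2b. Aldh1a2 (-3.28 instead of -5.05), Foxc2 (-2.39 instead of -4.06), Arg1 (-2.82 instead of -3.92) and Hoxd4 (-2.25) kept their calls there with smaller falls. Tbx6 also lost its call without untreated library 2 or any of the 4 XAV939 libraries, at adjusted p between 0.058 and 0.156. Hoxc6, Cyp26a1 and Wnt2b lost theirs without XAV939 library 4, at adjusted p between 0.0513 and 0.0675. Hoxc6 fell by 5.89 without XAV939 library 1. With no filter on low counts the call of Tbx6 ended (0.0671).

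Endoderm and epithelial lists were called down at day 5 as well. Of 17 tested genes of definitive endoderm and gut, all had negative fold changes and 9 fell, 16 adjusted over the list alone (camera adjusted p 1.7e-18). Sox17, a factor of endoderm and vessels, fell from 10.5 ± 6.09 to 1.75 ± 0.831 CPM. Of 12 epithelial genes, which share 5 members with the gut list, 5 fell and 11 adjusted over the list alone (adjusted p 1.32e-15). The tight-junction gene Cldn6 fell from 46.2 ± 23.3 to 12.8 ± 4.92 CPM, the keratin Krt8 from 103 ± 35.5 to 32.6 ± 7.86 CPM and Cdh1, the E-cadherin gene, from 319 ± 67.2 to 157 ± 68 CPM. Surface ectoderm genes included Cdh1 and Grhl3, a grainyhead factor of the epidermis, which fell 4.53-fold, and 2 of 12 fell, 6 adjusted over the list alone (adjusted p 6.28e-08). These 3 lists, both Hox lists above and the somitic list each kept their call with an estimated correlation (adjusted p = 0.041), as 6 of the 25 lists called at day 5. Gata4, a factor of heart and endoderm, fell 5.51-fold within a cardiac list called down (3 of 14 members, 5 adjusted over the list alone, adjusted p 0.000509, and adjusted p = 0.179 with an estimated correlation). The calls of Sox17, Cdh1, Grhl3 and Gata4 ended without untreated library 1 (0.0659 to 0.0948). Those of Sox17, Cdh1 and Gata4 also ended without untreated library 2 (0.058 to 0.167) or XAV939 library 4 (0.108 to 0.175), that of Gata4 without XAV939 library 1 (0.0564) and that of Cdh1 without XAV939 library 2 (0.102).

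At day 5 the pan-neural progenitor list was called up, while the neuron and neural crest lists were not called (camera adjusted p 0.143 and 0.672). Of 16 tested pan-neural progenitor genes 2 rose, Pou3f2 from 6.25 ± 4.19 to 23.8 ± 9.37 CPM and Pou3f3 from 2.47 ± 1.13 to 8.24 ± 3.16 CPM, both POU-domain factors. Adjusted over the list alone 6 members rose (camera adjusted p 2.08e-05, and adjusted p = 0.107 with an estimated correlation). A forebrain list was not called (adjusted p 0.578). Its member Otx2 was at 24.8 ± 3.78 CPM with XAV939 and 52.3 ± 26.2 CPM without (adjusted p 0.156). Among called genes of at least 5 CPM whose groups do not overlap, the largest rises were those of Vgll3 (chromosome 16, 65815257 to 65866368), a cofactor of TEAD factors, by 2.81 (SE 0.469, adjusted p 0.00178), and Nr2f1 and Nr2f2, orphan nuclear receptors, by 2.51 (SE 0.545) and 2.03 (SE 0.437). Also among them were the endothelin receptor gene Ednrb by 2.32 (SE 0.474), the matrix gene Thbs1 by 2.10 (SE 0.334) and the myosin motor Myo5b by 1.98 (SE 0.338). The neural factor Sox1 was at 97.1 ± 20.8 CPM with XAV939 and 38.3 ± 19.8 CPM without (adjusted p 0.124, and 0.0184 with the replicate number as a block within each day). Axin2 was at 74.7 ± 19.8 and 84.8 ± 18.5 CPM and Tcf7 at 57.8 ± 20.5 and 80.4 ± 16 CPM. The Wnt/β-catenin target list was called down with 13 of 14 members negative and 0 members called over all genes or adjusted over the list alone (adjusted p 0.000201, and adjusted p = 0.179 with an estimated correlation). T was at 196 ± 69.8 CPM with XAV939 and 395 ± 89.1 CPM without (adjusted p 0.649). The calls of Pou3f2 and Pou3f3 ended without untreated library 1 (0.0624 and 0.0767), untreated library 2 (0.0906 and 0.178) or XAV939 library 4 (0.107 and 0.183). That of Pou3f3 also ended without untreated library 4 (0.103) or XAV939 library 2 (0.0799), or with no filter on low counts (0.07). Nr2f1 lost its call without untreated library 2 (0.0591), and Ednrb and Nr2f2 theirs without XAV939 library 4 (0.0578 and 0.0704). Vgll3 rose by 3.40 without untreated library 3.

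**Figure D2:**
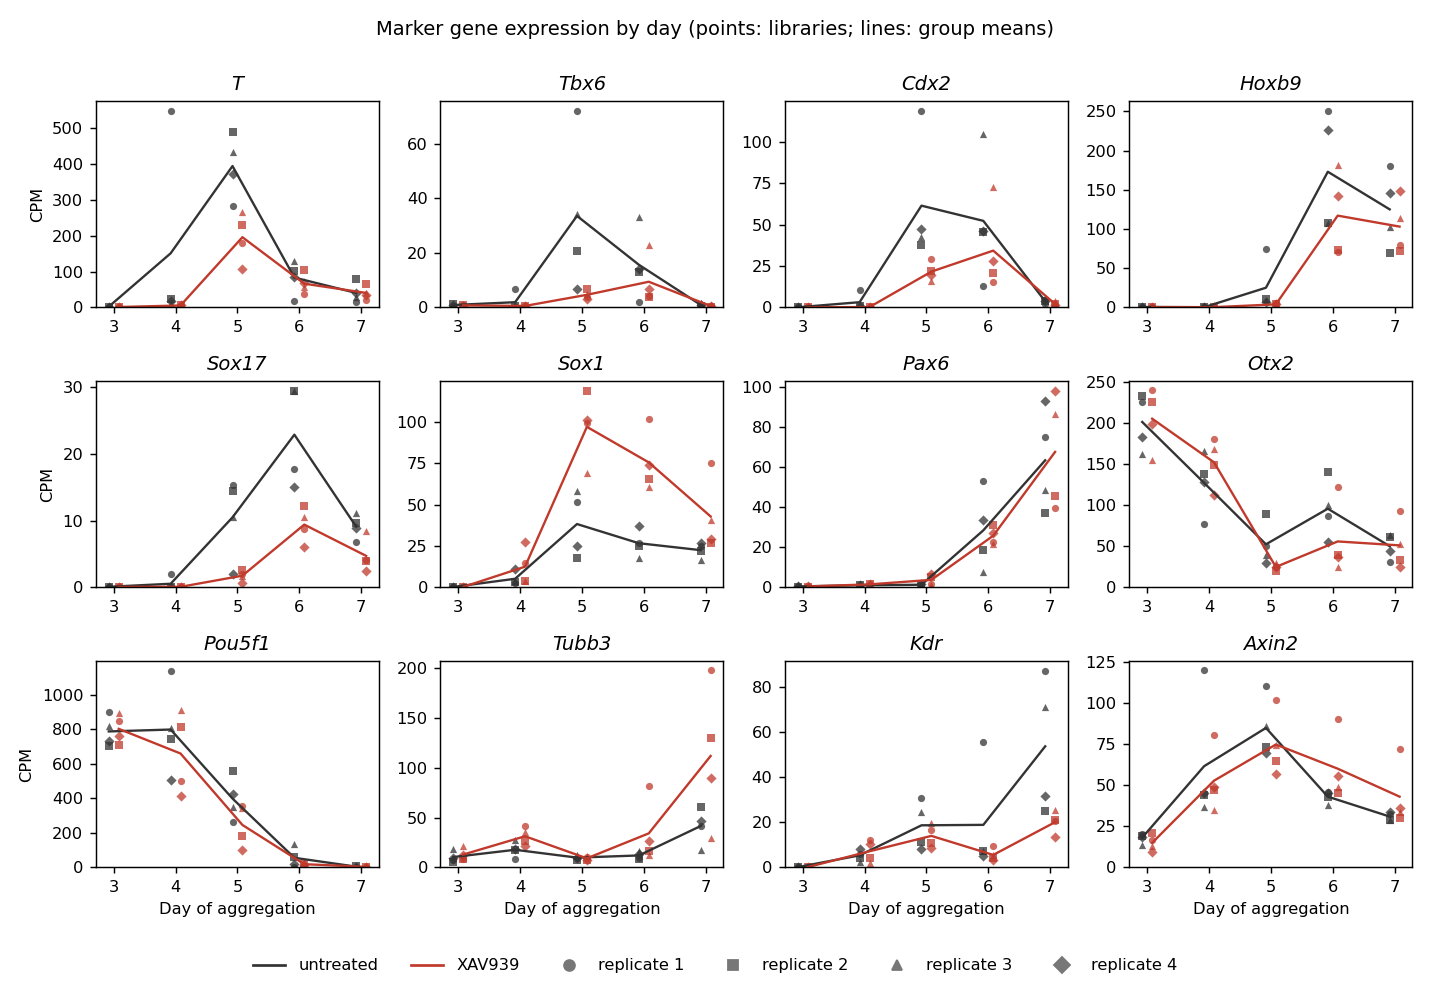
Levels of 12 panel genes in CPM against the day of aggregation, with 1 point for each library, shaped by its replicate number, and a line through the mean of each arm. T in day 4 untreated library 1 stands at 550 CPM and in the other 3 day 4 untreated libraries between 11.8 and 24.6 CPM.

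In all, 154 genes rose and 241 fell at day 5. The groups did not overlap for 7.46% of the genes tested, where chance gives 2.86% if libraries are unpaired. At days 3 and 4 the share was 1.29% and 2.03%. Of the 28 called genes named for this day, 9 kept their call whichever of the 8 libraries was left out: Vgll3, Thbs1, Myo5b, Aldh1a2, Arg1, Hoxd4, Cldn6, Krt8 and Foxc2. With the replicate number as a block 257 genes rose and 421 fell, with the block within each day 495 and 745, and a fit of the 8 day 5 libraries alone called 0, or 91 and 322 with a block, which kept 7 of the 28 calls. Of the 9 genes above, Vgll3, Thbs1, Myo5b, Aldh1a2, Arg1 and Hoxd4 lost their call in that fit with a block (0.0648 to 0.093). Foxc2 was not tested there. The counts of higher and lower genes were 51 and 44 without untreated library 1, 29 and 95 without untreated library 2, and 96 and 353 without untreated library 4. They were 67 and 153 without XAV939 library 2, 177 and 160 without XAV939 library 3, and 26 and 57 without XAV939 library 4.

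At day 6 camera called 15 lists down and 3 up, and none of the 18 kept its call with an estimated correlation. The other list test, fry, which does not compare members with the other genes, called 13 of the 18. All 12 tested epithelial genes fell, with a median of -1.57 (camera adjusted p 1.45e-21, 12 adjusted over the list alone, and adjusted p = 0.0511 with an estimated correlation). Epcam (chromosome 17, 87635979 to 87651129), an epithelial adhesion molecule, fell from 70.6 ± 33.3 to 21.3 ± 5.71 CPM (log2 -1.73, SE 0.259, adjusted p 0.000197). The claudin gene Cldn7 fell from 16.5 ± 10.6 to 3.14 ± 0.887 CPM and the grainyhead factor Grhl2 from 18.8 ± 5.64 to 6.94 ± 1.61 CPM. Of 17 gut genes 9 fell, 12 adjusted over the list alone (adjusted p 5.93e-14, and adjusted p = 0.0568 with an estimated correlation). Among them Cpm, the carboxypeptidase M gene, fell from 69.7 ± 24.7 to 21.7 ± 3.32 CPM and Hhex, a homeobox factor of anterior endoderm, from 31 ± 13 to 5.85 ± 2.29 CPM. Of 14 cardiac genes 4 fell, 10 adjusted over the list alone (adjusted p 8.29e-08, and adjusted p = 0.0568 with an estimated correlation). Gata4 fell from 17.3 ± 8.58 to 1.78 ± 0.79 CPM and the T-box factor Tbx20, from 6.03 ± 5.8 to 0.858 ± 0.413 CPM. Of 10 Nodal/Activin targets 4 fell, 8 adjusted over the list alone (adjusted p 1.31e-06, and adjusted p = 0.105 with an estimated correlation). Eomes, a T-box factor of mesendoderm, fell by 2.54 (SE 0.49, adjusted p 0.00176). Fgf5, a marker of primed epiblast, fell from 51.1 ± 23.5 to 12.3 ± 4.56 CPM, in a core epiblast list that was not called (2 of 17 fell, adjusted p 0.114, and 0.00425 without replicate 1). Pou5f1 was at 18.6 ± 10.1 CPM with XAV939 and 55.6 ± 59.7 CPM without (adjusted p 0.15). The steepest falls among called genes of at least 5 CPM whose groups do not overlap were those of Pga5, a pepsinogen gene (11.4-fold), Tnc, the tenascin C gene (10.6-fold), and Gata4 (9.72-fold). They also included Robo3, an axon-guidance receptor (8.9-fold), Nxf7, of a family of RNA export factors (8.76-fold), and Alx1, a homeobox gene of head mesenchyme (7.79-fold). Each call of a gene named here held whichever library was left out, while the log2 fold changes of Tnc and Tbx20 were -2.46 instead of -3.40 and -1.96 instead of -2.81 without untreated library 1. Pou5f1 was called without untreated library 1 (0.0309). Without untreated library 3, which held 138 CPM, its log2 fold change was -0.585 instead of -1.58 (adjusted p 0.911).

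Neuron genes rose in 8 of 17 cases at day 6, 10 adjusted over the list alone, with a median of 1.51 (camera adjusted p 6.37e-09, and adjusted p = 0.115 with an estimated correlation). Dcx (chromosome X, 143855842 to 143933311), the doublecortin gene of migrating neurons, rose by 3.38 (SE 0.585, adjusted p 0.000555), from 1.15 ± 0.583 to 12.1 ± 14.9 CPM. The microtubule gene Map2 rose from 13.6 ± 5.4 to 51.9 ± 38.9 CPM. Of 16 pan-neural progenitor genes 5 rose, 7 adjusted over the list alone (adjusted p 1.02e-05, and adjusted p = 0.105 with an estimated correlation). Nes, the nestin gene, rose from 120 ± 36.7 to 273 ± 78 CPM and Pou3f3 from 7.41 ± 3.19 to 32.4 ± 22.5 CPM. Sox1 was at 75.6 ± 18.5 CPM with XAV939 and 26.7 ± 8.01 CPM without, at an adjusted p of 0.0503. This p was 0.0171 with the replicate number as a block, 0.00894 with the block within each day, 0.0383 in DESeq2 and as low as 0.0348 with untreated library 4 or XAV939 library 3 left out. With any of the other 6 left out it was not called, at up to 0.182. Of 14 midbrain and hindbrain genes 4 rose, and 4 adjusted over the list alone (adjusted p 0.0064, and adjusted p = 0.359 with an estimated correlation, and 0.0938 without replicate 1). The engrailed genes En2 and En1 rose 14.5-fold and 36.2-fold and Pax5, a paired-box factor of the midbrain-hindbrain boundary, 8.06-fold. En2 stood at 64.6 and 34.6 CPM in XAV939 libraries 1 and 4 and at 2.01 and 3.16 CPM in libraries 2 and 3. Untreated libraries held 0.773 to 2.55 CPM of it, so the groups overlapped. Pax5 stood at 177 and 93.9 CPM in libraries 1 and 4 and at 19.6 and 23.3 CPM in libraries 2 and 3, against up to 18.8 CPM untreated. Rax, a factor of the eye field, fell 5.73-fold, in a forebrain list that was not called (adjusted p 0.42). Among called genes of at least 5 CPM whose groups do not overlap, the largest rises also included Vgll3 (5.46-fold), Lix1 (5.16-fold), Nefm, a neurofilament gene that overlaps Nefl on the other strand (4.66-fold), and Insl6, an insulin-like peptide gene (3.71-fold). Bambi, a decoy receptor for BMP and a Wnt target, fell from 20.1 ± 7.11 to 9.03 ± 1.27 CPM, and Apcdd1, a membrane antagonist of Wnt, rose from 15.4 ± 0.737 to 66.2 ± 77.1 CPM. Both are in the Wnt/β-catenin target list, of which 1 rose and 2 fell and which was not called (adjusted p 0.104, and 0.018 without replicate 1), and Axin2 was at 60 ± 20.5 and 43 ± 3.71 CPM. XAV939 library 1 held 94.3 CPM of Nefm against 12.4 to 20 CPM in the other 3. Without it the calls of En2, Lix1, En1, Pax5, Nefm and Apcdd1 ended, at adjusted p between 0.0799 and 0.48. The log2 fold change was then 2.04 for Dcx, which kept its call, 2.88 instead of 3.86 for En2, 4.21 instead of 5.18 for En1 and 2.23 instead of 3.01 for Pax5. It was 1.03 instead of 2.22 for Nefm and 0.899 instead of 2.10 for Apcdd1. Calls also ended for En1 and Pax5 without untreated library 1 (0.0611 and 0.0638), and for Apcdd1, Pax5 and En1 without untreated library 2 (0.0549 to 0.0701). They ended for Apcdd1, Rax and Pax5 without untreated library 3 (0.0561 to 0.0849), and for En1, Pax5 and Rax without XAV939 library 4 (0.0543 to 0.0728). With no filter on low counts the call of Pax5 ended (0.0535), and with length and GC offsets that of Apcdd1 (0.061). The calls of En1 (0.0542), En2 (0.0699) and Apcdd1 (0.1) ended with the block within each day, at log2 fold changes of 4.21, 2.74 and 1.33. Vgll3 rose by 3.27 without untreated library 4 and En1 by 5.80 without untreated library 3, and Rax fell by 3.27 without XAV939 library 2.

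**Figure D3:**
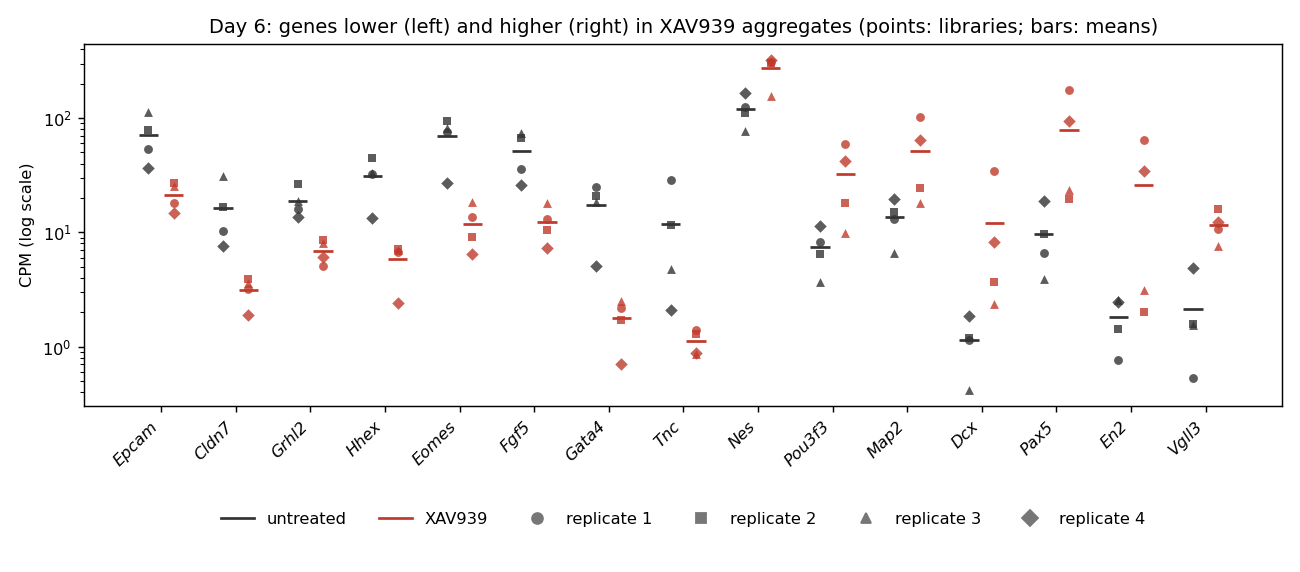
Levels in CPM on a log axis of 15 genes named at day 6, the genes that fell on the left and those that rose on the right, with 1 point for each of the 8 day 6 libraries and a bar at the mean of each arm. Hhex stands between 13.3 and 44.6 CPM in untreated and between 2.42 and 7.13 CPM in XAV939 libraries.

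In all, 235 genes rose and 498 fell at day 6. The groups did not overlap for 5.92% of the genes tested. With the replicate number as a block 387 genes rose and 703 fell, and with the block within each day 732 and 995. A fit of the 8 day 6 libraries alone called 0, or 101 and 210 with a block. The latter kept 16 of the 28 calls of genes named for this day. Tnc (0.0538), Vgll3 (0.0546), Tbx20 (0.068), Dcx (0.077) and Map2 (0.082) lost their call there, though not with any 1 library left out. The stricter filter left out Alx1 and Rax. The counts of higher and lower genes were 153 and 423 without untreated library 1, 137 and 337 without untreated library 2, 112 and 328 without untreated library 3, and 367 and 802 without untreated library 4. They were 48 and 283 without XAV939 library 1, and 111 and 220 without XAV939 library 4. Untreated library 3 had the lowest mean correlation with its own group of all 40 libraries, and length and GC content of the transcripts explained 60.4% of its deviation from the other 3.

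At day 7 camera called 15 lists, 5 up and 10 down, while 1 gene passed the test without pairing. All 17 tested neuron genes were higher in XAV939 aggregates, with a median of 1.10 (camera adjusted p 7.99e-15, 11 adjusted over the list alone, and adjusted p = 0.0351 with an estimated correlation). Stmn2, a microtubule regulator of neurons, was at 56.9 ± 37 CPM with XAV939 and 18.4 ± 6.86 CPM without (adjusted p 0.0888). Map2 was at 87 ± 50.5 and 34.7 ± 8.38 CPM, and Tubb3, the neuronal tubulin gene, at 112 ± 70.8 and 41.6 ± 18 CPM. XAV939 library 1 held 162 CPM of Map2 against 51.8 to 67.7 CPM and 198 CPM of Tubb3 against 29.2 to 130 CPM in the other 3, and had 1.21% mitochondrial counts against 2.41% to 2.51%. All 16 pan-neural genes were higher too, Nes at 347 ± 78.2 against 203 ± 57 CPM (adjusted p 1.99e-07, 3 adjusted over the list alone, and adjusted p = 0.0478 with an estimated correlation). All 12 epithelial genes were lower (adjusted p 1.77e-15, 12 adjusted over the list alone, and adjusted p = 0.0351 with an estimated correlation). Krt18 was at 180 ± 58.4 against 306 ± 107 CPM and Cdh1 at 101 ± 24.8 against 170 ± 41 CPM. Of 14 cardiac genes 13 were lower (adjusted p 1.73e-13, 9 adjusted over the list alone, and adjusted p = 0.0117 with an estimated correlation), with the actin gene Actc1 at 2.64 ± 0.878 against 5.87 ± 3.83 CPM. All 12 endothelial genes were lower (adjusted p 1.09e-10, 8 adjusted over the list alone, and adjusted p = 0.0318 with an estimated correlation). Kdr was at 20.1 ± 4.92 against 53.8 ± 30.2 CPM and Egfl7, a secreted protein of vessels, at 12.8 ± 2.48 against 20.7 ± 3.87 CPM. These were 5 of the 7 lists, of 15 called at day 7, that kept their call with an estimated correlation. The single gene called was Unc45b (chromosome 11, 82910550 to 82943403), a myosin chaperone of muscle named here after its values were seen, which fell by 2.23 (SE 0.396, adjusted p 0.0391), from 5.77 ± 4.89 to 1.23 ± 0.895 CPM. Its call ended without untreated library 1 (0.147), untreated library 3 (0.0691) or XAV939 library 1 (0.184), and its log2 fold change was -1.46 without untreated library 1 and -2.84 without XAV939 library 2. In a fit of the 8 day 7 libraries with a block Unc45b was not called (0.103), and the stricter filter left it out. Stmn2 and Nes were called without XAV939 library 3 (0.0275 and 0.0479) and not with any other library left out, at up to 0.783. A block of replicate number within each day gave calls of Stmn2 (0.0403), Map2 (0.0259), Nes (0.00191), Krt18 (0.0361), Cdh1 (0.0374), Kdr (0.029) and Egfl7 (0.0385).

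**Figure D4:**
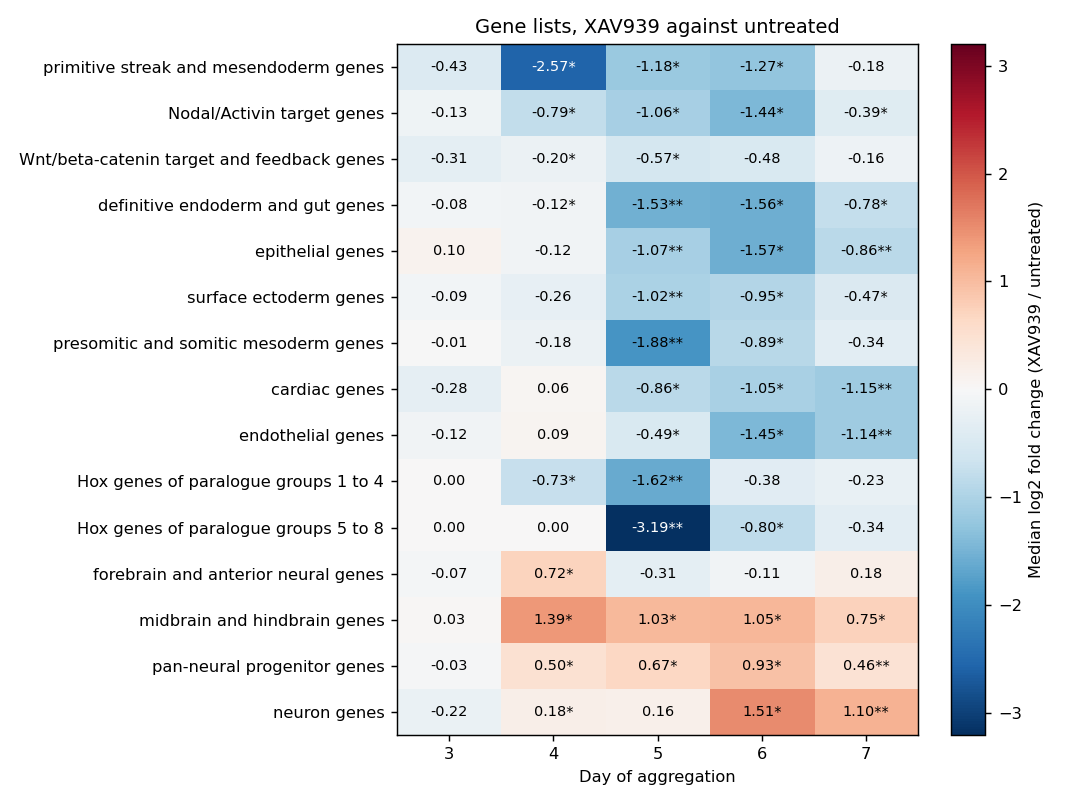
Median log2 fold change, XAV939 over untreated, of 15 of the gene lists by day, shown as a colour and a number, with 1 asterisk where camera called the list and 2 where it also did so with an estimated correlation. At day 5, 6 of these lists carry 2 asterisks, at day 7, 5 of them, and at days 3, 4 and 6, 0.

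edgeR called 0 genes higher and 1 lower at day 7, with 1326 genes at an unadjusted p under 0.05 and non-overlapping groups in 4.9% of the genes tested, and DESeq2 called 59 higher and 42 lower. With the replicate number as a block edgeR called 38 higher and 60 lower, and with the block within each day, which is how the libraries pair, 159 and 222. A fit of the 8 day 7 libraries called 0, and 355 and 322 with a block. The counts were 0 and 3 without untreated library 2, and 0 and 4 without untreated library 4. They were 28 and 13 without XAV939 library 2, 62 and 21 without XAV939 library 3, 13 and 1 without XAV939 library 4, and 0 in either direction without untreated library 1, untreated library 3 or XAV939 library 1.

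Whether the effect of XAV939 itself changed with the day was tested as a difference of effects. Between day 3 and day 7 edgeR called 0 genes, with 718 of 16878 at an unadjusted p under 0.05. That is below the share of 0.05 that no effect would give, in a fit that leaves the pairs out. DESeq2 called 1 gene higher and 0 lower. The block within each day gave 4 higher and 5 lower. camera called 5 lists up and 7 down for this change. The epithelial list had all 12 members negative (adjusted p 1.56e-11, and adjusted p = 0.161 with an estimated correlation). The neuron list had all 17 members positive (adjusted p 1.45e-09, and adjusted p = 0.177 with an estimated correlation). None of the 12 kept its call with an estimated correlation. In tests chosen after these results were seen, the effect at day 6 was higher than at day 3 for 2 genes and lower for 50, and higher than at day 4 for 5 and lower for 58. With the block within each day these counts were 215 and 351 against day 3, and 102 and 320 against day 4. The effect at day 5 differed from those at days 3 and 4 for 0 genes, and with that block was higher for 41 and lower for 79 against day 3, and 11 and 71 against day 4. The effects on Epcam, Cpm and Nxf7 were lower at day 6 than at either, with differences from day 3 of -1.85, -1.60 and -3.16 on the log2 scale (adjusted p 0.026, 0.0325 and 0.0279). The effects at days 6 and 7 differed for 0 genes in edgeR, and for 0 again with that block. Without the block 362 genes had an unadjusted p under 0.05, again below a share of 0.05. The effect at day 7 was higher than at day 5 for 2 genes (15 higher and 5 lower with the block) and differed from that at day 4 for 0 (5 and 11). Days 5 and 6 differed for 0 genes (5 and 6), and days 3 and 4 for 0 with either. DESeq2 was not run for the differences between other days.

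Over the 5 days together 979 genes differed at 1 day or more, 2260 with the replicate number as a block within each day, and 66 to 719 with 1 replicate number left out. The genes called at days 5 and 6 overlapped: 60 were higher and 67 lower at both days, and 0 changed in opposite directions. Unrelated lists of those sizes would share 2.14 and 7.11, if genes and the libraries of the 2 days are independent. Genes move together, and a pairing of libraries between days 5 and 6 was not tested, so the overlap cannot be read against chance. A block of replicate number gave 112 and 174 shared, and with the block within each day 244 and 323. Vgll3 and Pou3f3 were among the shared rises and Gata4 among the shared falls. Across all genes tested the fold changes correlated at 0.28 between days 4 and 5, 0.501 between days 5 and 6 and 0.593 between days 6 and 7 (Pearson's r across genes, which are not independent replicates).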

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

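The tests of an early or late library and of a day 5 library labelled day 4 were chosen after the values were seen, as were the tests between days. For each measure of library quality and each named gene, the highest or lowest of a group's 4 libraries was compared with the others: its gap to the nearest, divided by the range of the group, was set against Dixon's 95% value. Of 360 groups checked 41 went past it, where values with a normal spread give about 1 in 20, or 18. CPM need not have such a spread, many genes were named for differences between these libraries, and genes of 1 library move together. Neither 41 against 18 nor the counts by library number that follow can therefore be read against chance. Of these 41, 29 came from libraries numbered 1, 2 from number 2, 6 from number 3 and 4 from number 4.

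Day 4 untreated library 1 went past it in 10 measures. The gap was 0.976 of the range for T, 0.987 for Mixl1, 0.983 for Tbx6, 0.944 for Sox17, 0.925 for Cdx2, 0.901 for Axin2, 0.848 for Mcc and 0.839 for Lef1, all of them higher in this library, and 0.839 for its lower share of mitochondrial counts (1.53% against 2.99% to 3.27%) and 0.959 for its lower mean correlation with the group. An exchange with a day 5 untreated library was argued against, since 0 of those libraries lay closer to the other day 4 untreated libraries than to their own group, and so was a trend with transcript length and GC content, which explained 10.5% of its deviation. A library ahead of the others in development stays open: its deviation correlated across genes with the step from day 3 to day 5 at 0.373, against -0.491, -0.453 and 0.179 for the other 3. Its mean correlation with its own group less that with day 5 untreated libraries was -0.000975, which could not tell a day 5 library labelled day 4 apart from that. Hoxb9 stood at 0.23 CPM here against 7.29 to 75 CPM in day 5 untreated libraries, and Sox1 at 2.36 against 17.7 to 58.5 CPM. Cdx2 stood at 10.7 against 37.7 to 119 CPM and Pou5f1 at 1140 against 262 to 560 CPM. The first principal component was -42.78 against -9.682 to 33.85. These values argue against a day 5 library like those sampled. Lef1, Sox17, Otx2, Tubb3, Sox10 and the second component (55.41) lay within the day 5 range. On the first component day 4 XAV939 library 1, of the same number, lay at -43.63. XAV939 libraries 2, 3 and 4 of day 4 lay at -79.78, -76.94 and -41.83. A difference in culture between replicates may also be the source and was not tested.

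Day 5 untreated library 1 was higher than its group in 9 genes, by gaps of 0.957 for Hoxb9, 0.94 for Hoxb8, 0.933 for Hoxc4, 0.93 for Meox1, 0.923 for Hoxc6, 0.918 for Hoxaas3, 0.881 for Cdx2, 0.861 for Foxc2 and 0.857 for Aldh1a2. Day 7 XAV939 library 1 stood apart in Sox10 (0.856), Map2 (0.855) and Axin2 (0.844), which were higher, and in the share of mitochondrial counts (0.923), which was lower. Day 6 XAV939 library 1 was higher in Nefm (0.907) and Otx2 (0.854). Day 6 XAV939 library 3 was higher in Tbx6 (0.851) and Mixl1 (0.83) and lower in Nes (0.911). Day 4 XAV939 library 1 was higher in Hesx1 (0.913), at 22.3 CPM against 1.31 to 3.14 CPM, and in Six3 (0.839). Day 3 XAV939 library 4 was higher in Sox1 (0.977) and Kdr (0.918), both under 1 CPM.

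The other 9 measures came from a different library each time. Near 0 counts stood Arg1 in day 3 untreated library 4 and Six3 in day 3 XAV939 library 2, each with a gap of 1, since the other 3 libraries had 0 counts. Cdh1 was higher in day 5 untreated library 2 (0.867) and Hoxb9 lower in day 5 XAV939 library 3 (0.959). Kdr was higher in day 6 untreated library 1 (0.956), at 55.6 CPM against 5.16 to 7.37 CPM. Hhex was lower in day 6 XAV939 library 4 (0.93). Actc1 was higher in day 7 untreated library 1 (0.979) and Tbx6 in day 7 untreated library 3 (0.843). Day 7 XAV939 library 3 had the larger total, 36.9 M against 33.5 to 34 M counts (0.853).

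The effect of XAV939 differed between days for 15 of 76 named genes, in an F test with 4 degrees of freedom over all genes. That test called 39 genes in all, with 1254 at an unadjusted p under 0.05. Many of the 76 were named for their effect at 1 day in these same data. The 15 of 76 can therefore not be read against the share of all genes. The adjusted p was 0.0391 for Aldh1a2, Arg1, Cpm, Nxf7, Pga5, Thbs1, Tnc and Vgll3, 0.0453 for Bambi, Dcx, Epcam and Robo3, 0.047 for Cyp26a1, 0.048 for Nes and 0.0498 for Hesx1. With the replicate number as a block within each day the same test called 438 genes. The fold change of Hesx1 had opposite signs at days 4 and 6. It was at 7.19 ± 10.1 CPM with XAV939 and 1.14 ± 1.03 CPM without at day 4, where it was not called (adjusted p 0.17) and XAV939 library 1 held 22.3 CPM, and at 2.44 ± 1.55 and 12.9 ± 5.11 CPM at day 6, where it fell (adjusted p 0.0265).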

How the results depend on the processing

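The block within each day, the block in fits of the libraries compared, the length and GC offsets, both together, the removal of the doubtful libraries and the tests between days were chosen after the results were seen, and the rest before. Of 459 calls among 920 gene results, 336 of them for day 7 against day 3, 459 stayed called in the same direction with size factors by relative log expression, 457 in DESeq2, 456 with the replicate number as a block and 448 with length and GC offsets. The block within each day, paired by number, kept 114 of 123 calls of XAV939 effects and added 27. It lost all 3 calls of day 4, as did the block across days. With 1 library left out fewer were kept: 3 to 36 of 51 calls were lost at day 5 and 1 to 28 of 69 at day 6. The most were lost without day 5 untreated library 1 (36), day 5 XAV939 library 4 (28) and day 6 XAV939 library 1 (28). At day 4 all 3 were lost without untreated library 1 or XAV939 library 1, 3 or 4. With the offsets 2 calls reversed, mt-Nd6 (0.0564) and Tnks (-0.0814) for day 7 against day 3 in XAV939 aggregates, and the cause was not tested. On simulated counts 80% to 90% of 4-fold and 53% to 63% of 2-fold changes were recovered at the 5 days. Many 2-fold changes were thus missed even there. Those counts held no pairs of libraries and no library that stood apart, so the shares need not hold for the real libraries. With relative log expression 0 of 25 counts moved by over 1.5 times. The cause of the other shifts was not tested, except that fewer libraries or fewer genes were in the fit where so named. The values that moved follow.

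With the replicate number as a paired block the counts of higher and lower genes were 0 lower at day 4, 257 and 421 at day 5, 387 higher at day 6, and 38 and 60 at day 7, and the genes shared by days 5 and 6 were 112 higher and 174 lower. With the block within each day they were 0 lower at days 3 and 4, 495 and 745 at day 5, 732 and 995 at day 6, 159 and 222 at day 7, 4 and 5 for the change of the effect, 2260 at any day, and 244 and 323 shared by days 5 and 6. Fits of only the libraries compared called 0 genes at every day in either direction, from fewer libraries. With a block these fits called 1 and 12 at day 3, 0 lower at day 4, 91 higher at day 5, 101 and 210 at day 6, and 355 and 322 at day 7.

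DESeq2 called 18 and 38 at day 4, 385 lower at day 5, 59 and 42 at day 7, 1 higher for the change of the effect, and 1525 at any day. Without a low-count filter 0 were lower at days 3 and 4, and 101 higher at day 5. With the stricter filter, which tests fewer genes, 0 were lower at days 3 and 7, 159 lower at day 5, 143 and 284 at day 6, and 610 at any day. With an absolute log2 fold change of at least 1, 3833 and 2985 genes were called for day 7 against day 3 in untreated and 3104 lower in XAV939 aggregates. Length and GC offsets gave 252 higher at day 5, 373 higher at day 6, and 15 and 14 at day 7. With the block within each day as well they gave 3 and 4 at day 3, 0 lower at day 4, 757 and 960 at day 5, 1092 and 1226 at day 6, 336 and 389 at day 7, 34 and 52 for the change of the effect, and 3058 at any day.

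Lists called with an estimated correlation numbered 0 at days 4 and 6, 6 at day 5, 7 at day 7, and 0 for day 7 against day 3 in either arm and for the change of the effect. fry called 0 at day 4, 13 at day 5, 8 at day 7, 40 for day 7 against day 3 in XAV939 aggregates and 0 for the change of the effect.

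With each library or replicate left out in turn the counts ranged as follows. Higher genes were 0 at day 3, 0 to 23 at day 4, 26 to 177 at day 5, 48 to 367 at day 6 and 0 to 62 at day 7. Lower genes were 0 to 1 at day 3, 0 to 44 at day 4, 44 to 353 at day 5, 220 to 802 at day 6 and 0 to 21 at day 7. For day 7 against day 3 they were 5548 to 6200 higher and 5216 to 5891 lower in untreated aggregates, and 5907 to 6470 higher and 5452 to 6095 lower in XAV939 aggregates. The change of the effect stayed at 0, and the effect at any day ran from 66 to 719. Lists called ran from 8 to 20 at day 4, 22 to 25 at day 5, 16 to 21 at day 6, 14 to 17 at day 7, 25 to 28 and 20 to 26 for day 7 against day 3, and 9 to 15 for the change of the effect. Without day 4 untreated library 1 and day 6 untreated library 3 together, 286 were higher and 402 lower at day 5, 142 higher at day 6, 1 and 2 at day 7, and 916 at any day.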

Other observations

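The tests of developmental pace, of the length and GC trend at day 6 and of the stage of day 6 untreated library 3 were chosen after the results were seen. Further groups of genes differed between the arms at day 6 and day 7. At day 6 all 12 tested endothelial genes had negative fold changes and 2 fell, the blood and vessel regulators Etv2 and Tal1, with 8 adjusted over the list alone. The list was called down (camera adjusted p 0.000861, adjusted p = 0.261 with an estimated correlation, and 0.22 without replicate 1). Intermediate and lateral mesoderm genes fell in 2 of 12 cases, Hand2 and Twist1, with 8 adjusted over the list alone (adjusted p 2.15e-05, and adjusted p = 0.0568 with an estimated correlation). At day 7 11 of the 12 were lower with 3 adjusted over the list alone (adjusted p 3.75e-06, and adjusted p = 0.0318 with an estimated correlation). Extraembryonic endoderm genes fell in 3 of 12 cases at day 6, Gata4, Hnf4a and Gata6 (adjusted p 0.00363, and adjusted p = 0.105 with an estimated correlation). All 12 were lower at day 7, 4 adjusted over the list alone (adjusted p 1.2e-06, and adjusted p = 0.0117 with an estimated correlation). BMP targets fell in 2 of 10 cases at day 6, Bambi and Id1 (adjusted p 0.00107, and adjusted p = 0.118 with an estimated correlation).

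At day 5 further lists were called down with few members past the test: the notochord and node list with 1 of 9, the BMP antagonist Nog (adjusted p 8.87e-06, and adjusted p = 0.107 with an estimated correlation), and Hox genes of paralogue groups 9 to 13 with 1 of 5, Hoxb9 (adjusted p 0.00105, and adjusted p = 0.103 with an estimated correlation). The naive pluripotency list was also called down, with 13 of 14 members negative and 0 called (adjusted p 0.000791, and adjusted p = 0.27 with an estimated correlation). The midbrain and hindbrain list was called up with 13 of 14 members positive and 0 called (adjusted p 0.000379, and adjusted p = 0.197 with an estimated correlation). At day 6 the Hox genes of groups 5 to 8 were all 11 negative with a median of -0.80 and 0 called (adjusted p 0.000447, and adjusted p = 0.359 with an estimated correlation), against a median of -3.19 at day 5. Without day 5 untreated library 1 the day 5 log2 fold changes of its members Hoxb8, Hoxa7 and Hoxc6 were -1.42, -2.44 and -2.78 instead of -2.93, -4.04 and -4.97. The difference between the days of this list was not tested.

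Day 6 untreated library 3 lay apart from its group. Transcript length and GC content explained 60.4% of its deviation from the other 3 libraries, which is consistent with a difference in RNA or library preparation. Its share of mitochondrial counts was the lowest of all 40 libraries, 0.915% against 1.72% to 2.84% in its group. The next highest share explained by length and GC content was 56.9%, in day 5 XAV939 library 4, without which the day 5 counts were 26 higher and 57 lower instead of 154 and 241. After that trend was removed the rest of the deviation correlated across genes at 0.278 with day 5 minus day 7, against -0.511, 0.243 and -0.0877 for the other 3, so an earlier stage may be part of it as well. Its mean correlation with its own group and with the day 5 untreated group differed by 0.00435, too little by itself to exclude an exchanged label. The library lay at 52.26 on the first principal component and 11.46 on the second. Day 5 untreated libraries lay between -9.682 and 33.85 and between 48.7 and 65.89. Pou5f1 stood at 138 CPM against 262 to 560 CPM there, Mixl1 at 7.88 against 50.9 to 85.6 and Pax6 at 7.79 against 0.847 to 1.76. These values argue against an exchange with a day 5 untreated library. Lef1, Tbx6 and Cdx2 lay within the day 5 range. Without this library and day 4 untreated library 1 the day 6 counts were 142 higher and 426 lower.

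The day 6 differences may reflect a shift in developmental pace, and neither a faster nor a slower course covers them all. Of the genes higher with XAV939 76.2% also rose from day 5 to day 7 in untreated aggregates, where 48.9% of all genes did, so a slower course, which needs the other sign and held for 23.8%, was argued against for them and a faster one stays open. Of the genes lower with XAV939 34.9% fell from day 5 to day 7, which argues against a faster course for them, and the 65.1% that rose leave a slower one open. A trend with transcript length and GC content was argued against as the whole source, as 94.1% of the genes kept their call and direction with such offsets. Of the 733 genes called at day 6, 98.2% (720) had the same sign at day 7, where the median log2 fold change was 0.94 instead of 1.52 for the higher and -0.71 instead of -1.49 for the lower genes, at a like median SE (0.353 and 0.362). Genes picked by their day 6 values have smaller medians at another day even where the effect stays, so a weaker effect cannot be read from this. The direct test of day 7 against day 6 called 0 genes.

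Other splits of the same libraries into groups of 4 were fitted in the same way. At day 5 the real split gave 395 genes and the highest of the other 34 gave 108, and at day 6 733 against 579, so that 1 of 35 splits gave as many. Chance can be excluded at the 0.05 level for both if the libraries are taken as unpaired. At day 3 the real split gave 1 gene and at day 7 also 1, and 5 and 8 of the 35 splits gave as many, up to 655 and 7. At day 4 it gave 3, and 8 of 35 gave as many, up to 298. Chance cannot be excluded for these 3 days in these fits, which leave the pairs out. With the block within each day 159 genes were higher and 222 lower at day 7, and 0 at days 3 and 4; splits were not fitted with a block. The split of day 3 with 655 genes set replicates 1 and 2 of both arms against replicates 3 and 4, a structure of the samples by replicate number. Among the 7 other splits that part all 4 same-numbered pairs the highest counts were 0, 0, 9, 3 and 2 at days 3 to 7. With the real split these make 8, too few for a share under 0.05. For day 7 against day 3 the real split gave 11350 genes in untreated aggregates against 0 at the highest, and 11961 in XAV939 aggregates against 2880, 1 of 35 each, which excludes chance. For an effect at any day the real split gave 979 and the highest other 12, 1 of 50, which excludes chance too if the pairs are set aside. For the change of the effect from day 3 to day 7 the real split gave 0 and the highest other 1, so all 50 splits gave as many.

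Libraries numbered 1 held the lowest share of mitochondrial counts in 9 of the 10 groups, with a mean of 1.53% over 10 libraries against 2.8%, 2.71% and 3.32% for numbers 2, 3 and 4. In the day 6 untreated group library 3 was lower.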
